A study of Mus musculus with 4 samples.

How the data were processed

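Total RNA of CD9-enriched mouse placental trophoblast at embryonic day 12.5 was measured on 4 one-colour oligonucleotide arrays, 2 of wild type and 2 of Met KO. The authors deposited 1 table of 45101 probe sets with 1 value per array, already normalized. RMA and the affy package are named in the submitters' processing notes, without versions and without further steps.

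The deposited values were not on the log2 scale that RMA gives, and they were not linear intensities either. On each array 3735 to 3836 probe sets lay above 65535, the largest value a 16-bit scanner image can hold, and the values spanned 19.7 to 19.8 log2 units. The natural logarithm of the deposited values ran from 1.38 to 15.14 with array medians of 5.58 to 5.63, the usual range of RMA log2 intensities. The deposited value was therefore read as e raised to the RMA log2 intensity, an inference from the values that no label states. The design fixed before the data were examined had foreseen log2 values or linear values to be put on log2, so the unit differed from what was assumed. The tests stayed the same, and log2 of the deposited value, chosen after seeing the data, changes sizes by one factor and no p. All fold sizes are 2 raised to the difference of RMA log2 intensities.

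Genes were named from the platform annotation supplied with the data. Of the probe sets 34945 named 1 gene, 932 several and 9160 none, and 64 were control probe sets. Of the single-gene probe sets 34741 matched a current gene through the Entrez number, with 0 symbols to update. For each of 18193 genes the probe set with the highest mean over all 4 arrays was used, with no filter on dim genes. The 6 genes with the same value on all arrays were kept. Of 533 symbols in the fixed lists 493 were measured, 1 through a synonym. As RMA carries no detection call, the brightest of 27 Bacillus control probe sets, which have no target in the sample, marked background on each array (4.24 to 4.49). A gene not above it on any array of one group was given only a bound, taken as the bright group's mean against the mean of the higher of that background and the gene's own level per array. No coordinates are given because no genome build was stated for the array, and the GRCm38.p6 gene table served only for names and for the order of 18145 genes.

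Met KO was compared with wild type with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without covariates, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. With 2 arrays per group the residual degrees of freedom were 2, to which the prior added 2.33. The SD of the difference within a pair was 0.313 for wild type and 0.446 for Met KO. Gene lists with at least 4 measured members were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg over 25 lists, and again with an estimated correlation and with the directional p of fry. With an estimated correlation camera uses the 2 residual degrees of freedom, so a list can fail there whatever its correlation. The dissociation list, with an estimated correlation of −0.013, went from an unadjusted camera p of 1.72e-05 to 0.0426. The sex-linked list was described only. The counts adjusted over the list alone used the same p-values with Benjamini-Hochberg within each list.

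The genes named in the text followed a rule set before the data were examined. It took Met, Cd9, Epcam, Gcm1, Syna, Synb, Ctsq, Tpbpa and Xist. It then took per direction the 12 largest log2 changes among genes past the threshold, with both groups apart and the higher group's mean above 7.53, the median of all gene means, skipping unnamed gene models. From each list it took up to 4 members with the smallest p. Genes named outside the rule are marked as such where they stand.

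The fits were tested on simulated data in which 100 genes were changed at each size. Of genes changed by 1 log2 unit 0% passed the threshold and of those changed by 3 units 83%, and 5 unchanged genes passed. Far more genes differed in the data (3111 higher and 2667 lower at an unadjusted limma p under 0.05). The adjusted threshold was therefore stricter in the simulation, and its 0% does not hold for the data, where Mcm3 passed at −0.79. A list raised by 1 unit passed camera (adjusted p = 3.28e-22), and 5 of the unchanged lists reached an unadjusted p under 0.05. The simulated genes were independent, so this does not test the preset correlation on the real lists, where the estimate was 0.83 for cell cycle genes.

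Alternatives set before the data were examined were the replicate number as a block, renewed quantile normalization, centring of arrays on their median, a dim filter, the mean of a gene's probe sets, all probe sets separately, an intensity trend, a robust prior, pseudocounts of 1 and 16 on log2 of the deposited value, stricter and unadjusted thresholds, other list tests, and leaving out each array. An adjusted p under 0.1 and a count without members of the 7 lists of other cell types were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.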

Results

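The dataset held 4 microarrays of RNA from mouse placental trophoblast, the epithelial cell lineage of the placenta, taken at E12.5 (embryonic day) and enriched for the surface protein CD9 on an immunomagnetic column. There were 2 arrays of wild-type placentas and 2 of placentas lacking Met (Met KO), the gene of the receptor for hepatocyte growth factor, and the labels call the samples of a group biological replicates. How many placentas went into one sample is not settled by the labels, whose extraction text speaks of "BM" of 4 individuals, a source that does not match sorted trophoblast. Levels are stated as RMA log2 intensities, read from the deposited values as their natural logarithm. This reading rests on the range of the values, and on the other reading, log2 of the deposited value, each size would be larger while each p would be the same. Each array listed 45101 probe sets, from which 18193 genes were taken. The wild-type pair correlated across genes at r = 0.995, the Met KO pair at 0.990, and arrays of different groups at 0.976 to 0.981. The precision is limited by the number of arrays. Unless stated, SE is the standard error of the log2 change from limma over n = 2 arrays per group.

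The comparison of Met KO with wild type addresses which transcripts of the CD9-enriched fraction differ when placentas lack Met. The Met transcript itself, on the brighter of its 2 probe sets, was at 9.22 and 9.43 on the wild-type arrays and at 6.75 and 6.84 on the Met KO arrays. It fell by 2.53 on the log2 scale (SE 0.14, 5.78-fold; limma, adjusted p = 0.0412). The deleted exons are not in the labels, so whether this probe set lies in the deleted part is open. The second Met probe set lay below the brightest bacterial control probe set on all 4 arrays and was therefore not read. On log2 of the deposited value the change of Met was −3.65. Cd9, the antigen of the column, fell from 9.83 ± 0.053 (SD, n = 2) to 8.62 ± 0.058 (SD, n = 2), a change of −1.22 (SE 0.12, adjusted p = 0.0419). Epcam, a surface protein of epithelial progenitors, was at 11.69 ± 0.019 and 10.82 ± 0.29 and did not pass the test (−0.87, adjusted p = 0.0626).

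Macrophage and granzyme genes were among the largest rises in Met KO, and an imprinted growth regulator, a claudin and a growth factor gene were among the largest falls. F13a1, the A chain of coagulation factor XIII, rose by 2.72 (SE 0.31), Mrc1, the macrophage mannose receptor, by 2.59 (SE 0.26) and Adgre1, a surface receptor gene that marks macrophages, by 2.46 (SE 0.30). Phlda2, a maternally expressed imprinted gene that restrains placental growth, fell from 12.34 ± 0.22 to 8.74 ± 0.30 (SD, n = 2 each), a change of −3.59 (SE 0.21, 12.1-fold). Cldn7, a claudin of tight junctions, fell by 2.93 (SE 0.22), and Tgfa, a ligand of the EGF receptor, by 2.75 (SE 0.21).

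In all, 471 genes were higher and 461 lower in Met KO at an adjusted p under 0.05, of which 369 and 306 differed at least 2-fold. Among the 12 largest rises named by the fixed rule were also Tmem255a (+2.51), Ly86 (+2.50), Ms4a6b (+2.48), the scavenger receptor gene Stab1 (+2.46), Gzmd (+2.44), Gzme (+2.39), Depp1 (+2.34), Igfbp1 (+2.28) and the complement gene C1qb (+2.27). The probe sets of Gzmd, Gzme and C1qb are of a type that can bind related transcripts, so the levels of these 2 granzymes are not independent with certainty. The 12 largest falls further comprised Cidea, a lipid droplet protein gene (−3.72), Elavl3 (−3.02), the kinase gene Wnk3 (−2.99), the homeobox gene Irx4 (−2.92), Lonrf3 (−2.90), Bzw2 (−2.78), Dlx4os (−2.77) and the kinase gene Sgk2 (−2.72). Rbm44 fell at least 11-fold, its Met KO level of 3.92 being no brighter than the bacterial controls against 7.80 in wild type. The highest adjusted p among these 24 genes was 0.0484. These sizes are those of each gene's brightest probe set, and for 3 of the falls dimmer probe sets differed. The others of Elavl3 were at −0.20 and −0.21, those of Bzw2 at −0.82 and −0.18, and those of Tgfa at −0.66 and +0.059. Of the 4 probe sets of Tmem255a the dimmest, at the level of the bacterial controls, had the opposite sign.

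**Figure D1:**
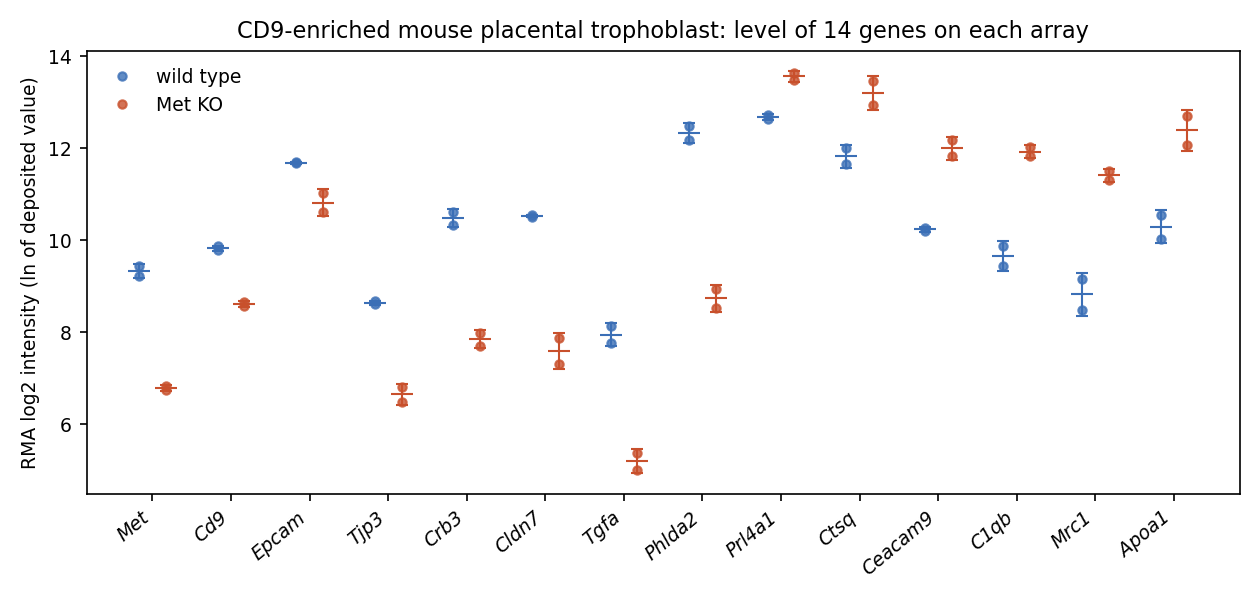
Level of 14 genes on each of the 4 arrays, as RMA log2 intensity (natural log of the deposited value); points are arrays, horizontal marks the group mean and bars the SD (n = 2 each). Met, Cd9 and Phlda2 lay lower and C1qb, Mrc1 and Apoa1 higher on both Met KO arrays, while Epcam and Ctsq did not pass the test (adjusted p = 0.0626 and 0.0528).

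**Figure D2:**
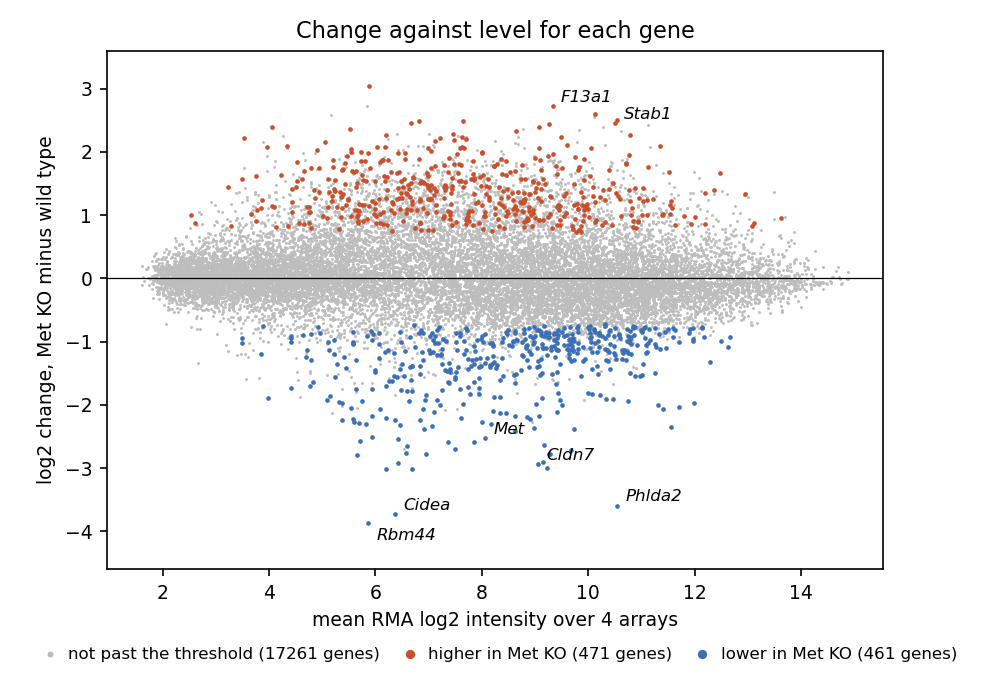
Log2 change of each of 18193 genes (Met KO minus wild type, vertical) against its mean RMA log2 intensity over the 4 arrays (horizontal). Red points are the 471 genes higher and blue points the 461 genes lower in Met KO at an adjusted p under 0.05, and the plotted change of Rbm44 is a fitted value where the text gives a bound.

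The trophoblast genes that passed the test went in both directions. Of 8 measured genes of syncytiotrophoblast layer I, the cell layer that faces maternal blood, 4 fell, namely Tgfa, the synaptic vesicle gene Snap91 (−2.22, SE 0.25), the monocarboxylate transporter gene Slc16a1 (−0.99, SE 0.15) and Glis1 (−0.77, SE 0.12). Adjusted over the list alone 5 fell, the list median was −0.65 and the list passed camera (adjusted p = 0.00103). It did not pass with an estimated correlation (adjusted p = 0.443), where the test had 2 degrees of freedom. With genes of a mean level under 7.53 left out the call also ended (median −0.49, adjusted p = 0.139). That filter removed Tgfa and Glis1, both brighter than the bacterial controls. On the same Met KO arrays the medians of the 7 lists of other cell types lay at +0.79 to +1.53, and Cd9 at −1.22. Of 8 genes of syncytiotrophoblast layer II, Dlx3, a homeobox gene needed for the labyrinth, fell by 2.36 (SE 0.25), while Cebpa (−1.60) and Ovol1 (−1.79) did not pass, at adjusted p = 0.0512 and 0.0524. That list had 1 rise and 3 falls when adjusted over the list alone, and did not pass camera (median −0.29, adjusted p = 0.217). Among 18 stem and progenitor genes, Satb1 (−1.94, SE 0.12), the trophoblast transcription factor gene Elf5 (−1.63, SE 0.19) and Gata2 (−1.09, SE 0.15) fell and Bmp4 rose (+1.45, SE 0.20). For these 18 genes the median was −0.056, 3 rose and 5 fell adjusted over the list alone, and the list did not pass camera (adjusted p = 0.453). One other probe set of Elf5 had the opposite sign (+0.11, did not pass), and another of Gata2 was at −0.52. With the mean of probe sets the calls of Elf5 (−0.76, adjusted p = 0.367) and Gata2 (−0.80, adjusted p = 0.0568) ended. The call of Snap91, whose other probe set was at background and at −0.12, ended with that mean too.

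Spongiotrophoblast and glycogen cell genes, of the endocrine junctional zone, were as a list higher in Met KO (27 genes, median +0.90, camera adjusted p = 6.56e-05; adjusted p = 0.443 with an estimated correlation). Ceacam9 (+1.77, SE 0.17) and the protocadherin gene Pcdh12 (+1.0, SE 0.12) rose and Phlda2 fell, with 6 rises and 1 fall adjusted over the list alone, and 21 of the 27 genes were higher on both Met KO arrays. These arrays also had the higher lists of other cell types (medians +0.79 to +1.53, decidual and uterine natural killer genes at +1.04), the lower Cd9 (−1.22) and a larger difference between the 3' and 5' Gapdh control probe sets, a measure of RNA integrity (1.63 and 1.59 against 1.47 and 1.37 in wild type). The dimmer probe sets of Pcdh12 were at +0.035 and +0.33, and its call ended with the mean of probe sets (+0.46, adjusted p = 0.0796). Tpbpa, the standard marker of spongiotrophoblast, was at 14.60 ± 0.028 and 14.73 ± 0.041 (SD, n = 2 each), near the top of the scale, and did not pass (+0.12, adjusted p = 0.532). Its other probe sets did not pass either, at +0.17 and, away from the top of the scale (10.42 and 10.84), at +0.43. Of 12 trophoblast giant cell genes the prolactin family member Prl4a1 rose from 12.69 ± 0.071 to 13.56 ± 0.12 (+0.88, SE 0.13), and Ctsq, a cathepsin of sinusoidal giant cells, did not pass (+1.38, adjusted p = 0.0528). The giant cell list had 2 rises and 2 falls adjusted over the list alone and did not pass camera (median +0.59, adjusted p = 0.0968). It passed camera with the replicate number as a block (adjusted p = 0.0191) and with all probe sets separately. Gcm1, Syna and Synb, transcripts of the syncytiotrophoblast layers, were not analysed here because no probe set with that single gene name was listed.

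Genes of epithelial junctions and polarity fell in part, 11 of 33 and none rising. The apical polarity gene Crb3 fell from 10.48 ± 0.19 to 7.85 ± 0.20 (−2.63, SE 0.18), the tight junction scaffold gene Tjp3 by 1.99 (SE 0.16) and the epithelial splicing regulator gene Esrp1 by 1.90 (SE 0.18), besides Cldn7. Adjusted over the list alone 4 rose and 13 fell, and the list passed camera as lower (median −0.27, adjusted p = 0.00109; adjusted p = 0.443 with an estimated correlation). With all probe sets taken separately the median was −0.13, and it was −0.17 on Met KO replicate 1 and −0.37 on replicate 2. The dimmer probe sets of Crb3 were at −0.35 and −0.86. On the same Met KO arrays the macrophage list was 1.48 and 1.65 above the wild-type mean and Cd9 1.22 below it. The 21 genes of the Met receptor pathway had Met, the protease gene St14 (−1.39, SE 0.22) and the protease inhibitor gene Spint2 (−1.19, SE 0.14) among them as falls and no rise, with 3 rises and 7 falls adjusted over the list alone. Their median was −0.057 and the list did not pass (camera adjusted p = 0.444). Targets of ERK, a kinase downstream of many growth factor receptors, were higher as a list (19 genes, median +0.66, or +0.39 with all probe sets separately, camera adjusted p = 0.0477; adjusted p = 0.443 with an estimated correlation). That call ended on renewed quantile normalization (adjusted p = 0.0520), and without either wild-type array or Met KO replicate 2 (adjusted p = 0.0533 to 0.0872). The members Fos, Egr1 and Ier3 are also on the list of dissociation genes, which was higher on the same arrays (median +0.68), as were the lists of other cell types. Within the ERK list Ier3 rose (+1.17, SE 0.16) while Myc (−1.26, SE 0.13) and Hbegf, another EGF receptor ligand gene (−2.20, SE 0.34), fell, and 7 rose and 2 fell adjusted over the list alone.

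Cell cycle genes were lower as a list, with 30 of 35 below both wild-type arrays on both Met KO arrays. Ccne1, which encodes cyclin E1, fell by 1.36 (SE 0.13), the replication licensing gene Cdc6 by 0.97 (SE 0.12), the spindle checkpoint gene Mad2l1 by 0.91 (SE 0.12) and the replicative helicase gene Mcm3 by 0.79 (SE 0.12). These 4 were the falls over all genes, 15 fell adjusted over the list alone and none rose by either adjustment. Camera placed the list lower (median −0.51, adjusted p = 7.29e-09; adjusted p = 0.464 with an estimated correlation). The list median was −0.69 on Met KO replicate 1 and −0.33 on replicate 2, so it was −0.33 without replicate 1. The same arrays carried the higher levels of markers of other cell types given below for each list. Of 21 CDK inhibitor and p53 target genes 0 passed limma over all genes or adjusted over the list alone (1 higher at an unadjusted p under 0.05), and the list did not pass (median +0.22, camera adjusted p = 0.199). The smallest adjusted p there was that of the death receptor gene Fas (+1.19, adjusted p = 0.0567).

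Markers of other cell types were higher in Met KO for each of the 7 lists fixed for them. Of 23 macrophage and leukocyte genes 9 rose, 22 adjusted over the list alone, among them C1qc (+2.18, SE 0.21), Mrc1, F13a1 and C1qb (median +1.44, camera adjusted p = 1.41e-10; adjusted p = 0.443 with an estimated correlation). Of 16 yolk sac endoderm genes 3 rose, the apolipoprotein genes Apoa4 (+2.11, SE 0.29) and Apoa1 (+2.09, SE 0.30) and the transthyretin gene Ttr (+1.34, SE 0.17), and 15 adjusted over the list alone (median +1.51, camera adjusted p = 5.14e-08; adjusted p = 0.443 with an estimated correlation). None of the 20 endothelial genes passed limma over all genes (19 higher at an unadjusted p under 0.05), 19 rose adjusted over the list alone, and 20 of 20 were higher on both Met KO arrays. Cldn5, a claudin of endothelium, had the smallest adjusted p of them (+2.15, adjusted p = 0.0512), and the list passed camera (median +1.53, adjusted p = 1.18e-08; adjusted p = 0.447 with an estimated correlation). Of 13 megakaryocyte and platelet genes the integrin gene Itgb3 rose (+0.86, SE 0.11), and 13 rose adjusted over the list alone (median +1.5, camera adjusted p = 1.36e-06; adjusted p = 0.443 with an estimated correlation). Thy1 (+1.37, SE 0.16) and the pericyte receptor gene Pdgfrb (+1.09, SE 0.14) rose among 20 mesenchyme and pericyte genes, and 18 rose adjusted over the list alone (median +1.11, camera adjusted p = 4.27e-08; adjusted p = 0.443 with an estimated correlation). Of 19 decidual and uterine natural killer genes Gzmb (+1.5, SE 0.14), Gzmd and Gzme rose and Alpl, alkaline phosphatase, fell (−0.79, SE 0.12). Adjusted over the list alone 9 rose and 2 fell (median +1.04, camera adjusted p = 0.00115; adjusted p = 0.447 with an estimated correlation). That median was +2.33 with genes of a mean level under 7.53 left out, and +0.86 on Met KO replicate 1 against +1.60 on replicate 2. For 18 erythroid genes 0 passed limma by either adjustment (2 higher at an unadjusted p under 0.05), the median was 0.14 on Met KO replicate 1 and 1.22 on replicate 2, and the list passed camera (median +0.79, adjusted p = 0.0274; adjusted p = 0.627 with an estimated correlation). Without wild-type replicate 1 or Met KO replicate 2 the erythroid call ended (adjusted p = 0.0856 and 0.210).

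**Figure D3:**
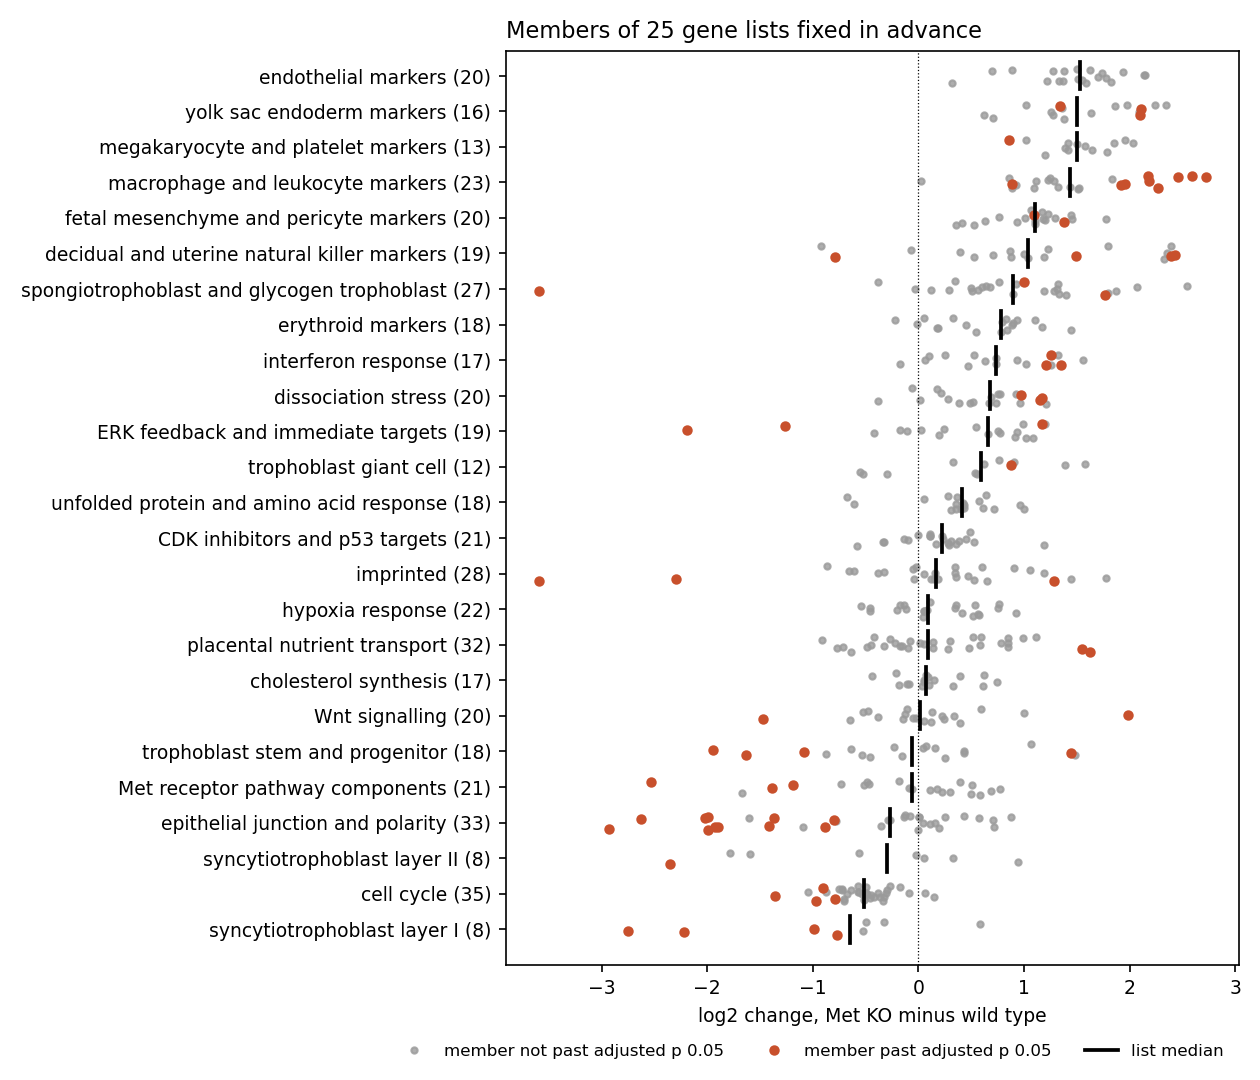
Log2 change (Met KO minus wild type) of each measured member of 25 gene lists fixed in advance, with the number of members in parentheses; red points passed an adjusted p of 0.05 over all genes and black bars are list medians. The medians run from −0.65 for syncytiotrophoblast layer I to +1.53 for endothelial markers.

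Interferon response genes were higher as a list, 3 of 17 rising, namely Usp18 (+1.35, SE 0.18), Oasl2 (+1.21, SE 0.17) and Oasl1 (+1.26, SE 0.20), and 10 adjusted over the list alone (median +0.74, camera adjusted p = 4.56e-05; adjusted p = 0.443 with an estimated correlation). Among 20 genes known to respond to tissue dissociation Ier3, Fosb (+1.15, SE 0.16) and Socs3 (+0.97, SE 0.15) rose, and 10 adjusted over the list alone (median +0.68, camera adjusted p = 5.36e-05; adjusted p = 0.443 with an estimated correlation). Of 18 genes of the unfolded protein and amino acid response 0 passed limma by either adjustment (7 higher and 2 lower at an unadjusted p under 0.05), and the list passed camera as higher (median +0.41, adjusted p = 0.0121; adjusted p = 0.443 with an estimated correlation). Macrophage and leukocyte genes had a median of +1.44 on the same arrays, 22 of 23 being higher on both Met KO arrays. The difference between the 3' and 5' Gapdh control probe sets was 1.63 and 1.59 on the Met KO arrays against 1.47 and 1.37 on the wild-type arrays.

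Imprinted genes, nutrient transporters and Wnt genes did not pass as lists. Of 28 imprinted genes Phlda2 and its neighbour Slc22a18 (−2.30, SE 0.22) fell and Zdbf2 rose (+1.29, SE 0.20), the same counts of 1 rise and 2 falls held adjusted over the list alone, and the median was +0.17 (camera adjusted p = 0.459). Among 32 genes of placental nutrient transport Fcgrt, the neonatal Fc receptor gene (+1.62, SE 0.18), and the endocytic receptor gene Cubn (+1.55, SE 0.24) rose, with 4 rises and 1 fall adjusted over the list alone (median +0.093, camera adjusted p = 0.647). The lists of other cell types were higher on the same Met KO arrays (medians +0.79 to +1.53, yolk sac endoderm genes at +1.51). Which cells gave the rises of Fcgrt and Cubn was not tested. Of 20 Wnt signalling genes Rspo3 rose (+1.99, SE 0.32) and Bcl9l fell (−1.47, SE 0.19), with the same counts adjusted over the list alone. Both calls ended with the mean of probe sets. The Wnt median was +0.011 while camera placed the list on the lower side (adjusted p = 0.726).

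The calls came from limma over all 4 arrays with Benjamini-Hochberg adjustment over 18193 genes. Each of the 932 genes past the threshold had both Met KO arrays above or both below the wild-type arrays. With so few arrays a gene whose groups overlap could not pass, so this separation follows from the call and is no separate check. Over all genes, 5697 lay higher and 5597 lower on both Met KO arrays, where chance gives 33.3% of genes in either direction together. At an unadjusted p under 0.05, 3111 genes were higher and 2667 lower. No gene passed without any 1 of the 4 arrays (smallest adjusted p 0.0712 to 0.255), and the smallest adjusted p with all arrays, 0.0412, lay close to the threshold. Of 25 lists 15 passed camera with its preset correlation, and 0 with an estimated correlation (1 at an unadjusted p under 0.05) or with fry (12 at an unadjusted p under 0.05).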

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

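Among the alternatives, log2 of the deposited value, the adjusted p under 0.1 and the count without other cell types were chosen after seeing the data. The counts of 471 higher and 461 lower genes stayed within 1.5 times under renewed quantile normalization (518 and 550), the mean of probe sets (594 and 621), all probe sets separately (468 and 581), a pseudocount of 1 (554 and 543), and without members of the other-cell-type lists (453 and 460). Of the 932 genes 919 were called again after quantile normalization, 931 after centring, 928 with an intensity trend, 722 with the mean of probe sets, 564 with the dim filter, which tested 9097 genes, and 542 with a robust prior. Centring on the median gave 692 lower genes, the dim filter 981 higher and 1280 lower, the intensity trend 1191 and 1201, the robust prior 263 and 279, and a pseudocount of 16 gave 793 and 841. An added log2 change of at least 1 left 369 higher and 306 lower genes, an unadjusted p with that change gave 1229 higher and 450 lower, and an adjusted p under 0.1 gave 2124 and 1811. Except for the fewer genes tested under the dim filter and the changed thresholds, the cause was not tested.

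With the replicate number as a block, limma called 0 genes higher and 0 lower (2901 and 2248 at an unadjusted p under 0.05), where 1 residual degree of freedom is left, and Met was at −2.53 with adjusted p = 0.0903. Deviations of same-numbered arrays correlated at −0.036 across genes and no label says that a number marks a shared litter or day, so the numbers were not taken to pair the arrays. Leaving out each array in turn gave 0 to 0 genes higher and 0 to 0 lower (limma; 1712 to 3191 higher and 1265 to 2724 lower at an unadjusted p under 0.05), and a lone array was taken to vary like the other group. Met then lay at −2.64 to −2.42 (adjusted p 0.0712 to 0.255), and 13 to 15 lists passed camera. With an estimated correlation 0 lists passed, and with fry 0.

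The syncytiotrophoblast layer I list lost its call with the dim filter (median −0.49, adjusted p = 0.139) and the ERK list with the block (adjusted p = 0.0584). The giant cell list gained one with the block, with all probe sets and without wild-type replicate 1 (adjusted p = 0.0191, 0.00358 and 0.0181), and the imprinted list with all probe sets (adjusted p = 0.00358). The syncytiotrophoblast layer I median was −1.14 with the mean of probe sets, and the erythroid median 0.45 with all probe sets. With the mean of probe sets the calls of Bcl9l (−0.49, adjusted p = 0.113), Snap91 (−1.17, adjusted p = 0.0634), Mcm3 (−0.70, adjusted p = 0.0644) and Rspo3 (2.06, adjusted p = 0.0649) ended, besides Elf5, Gata2 and Pcdh12. Of the named genes 22 lost their calls with the robust prior, 13 with all probe sets and 1 with quantile normalization, at adjusted p up to 0.0548. Calls were gained by 31 named genes with the intensity trend, 30 with the dim filter and 14 with the mean of probe sets. A pseudocount of 16 added 14, centring 11, and quantile normalization and a pseudocount of 1 added 6 each.

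Reversals of sign met lists and genes that had not passed. The Wnt median became −0.032 with centring, −0.031 with the dim filter, −0.11 with the mean of probe sets and −0.046 with all probe sets, and ran from −0.057 to 0.047 without single arrays. Nutrient transport became −0.0019 with the mean of probe sets, −0.0027 with all probe sets, and ran from −0.022 to 0.182 without single arrays. The stem and progenitor median became 0.045, Uty 0.022 and Eif2s3y −0.096 with the mean of probe sets. Without single arrays the Met pathway median ran from −0.096 to 0.118, Kdm5d from −0.280 to 0.032 and cholesterol synthesis from −0.040 to 0.178. Of the 932 genes, 42 were no brighter than the bacterial controls in wild type and 22 in Met KO, where sizes are least certain.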

Other observations

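The gene list tests here and the test of neighbouring pairs across the genome were set before their results were seen, and the tests of cell types, of dilution, of genes near Met, of symbol families and of splits after. Hypoxia and cholesterol genes did not pass as lists. Of 22 hypoxia response genes 0 passed limma by either adjustment (7 higher and 1 lower at an unadjusted p under 0.05), the median was +0.094 and camera gave adjusted p = 0.177. The kinase gene Pdk1 came closest (+0.75, adjusted p = 0.0505). Of 17 cholesterol synthesis genes 0 passed limma by either adjustment (3 higher and 1 lower at an unadjusted p under 0.05), the median was +0.073 and camera gave adjusted p = 0.468, with Srebf2 at +0.62 (adjusted p = 0.0914) and Idi1 at −0.44 (adjusted p = 0.0915). Xist was at 11.71 ± 0.079 in wild type and 10.93 ± 0.27 in Met KO (SD, n = 2 each; −0.78, adjusted p = 0.0705). The Y-linked genes Uty, Eif2s3y and Kdm5d lay below the brightest bacterial control on all 4 arrays.

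The 7 lists of other cell types passed camera as higher while 11 epithelial junction genes fell, but with adjusted p = 0.443 to 0.627 with an estimated correlation, with no endothelial or erythroid gene past limma over all genes (19 and 2 higher at an unadjusted p under 0.05), and with an erythroid call that ended without wild-type replicate 1 or Met KO replicate 2 (adjusted p = 0.0856 and 0.210). A lower share of trophoblast of every kind as the whole cause would lower giant cell and spongiotrophoblast genes, whose median was +0.76 (95% bootstrap interval over genes 0.559 to 1.0). That prediction was written after the list medians (+0.59 and +0.90) were seen, and the interval takes genes as independent and holds no spread between arrays. Both list medians lay above the wild-type mean on each Met KO array (giant cell 0.79 and 0.46, spongiotrophoblast 0.97 and 0.80). This goes against that cause but is no independent test. More RNA from other cell types remains open. Its prediction was written after the list results and asks for the same rises that it would explain, so meeting it is no test. Of the list members 85.9% (110 of 128) were higher on both Met KO arrays, as were 5697 of all 18193 genes. Ttr was at 13.62, Col3a1 at 12.86, Itgb3 at 12.63, C1qb at 11.93 and Cldn5 at 10.87 there. The CD9 column would keep platelets, macrophages and endothelium, which also carry CD9. Whether the yolk sac, mesenchymal or erythroid cells carried it was not tested. Of the 128 genes 125 were above background in wild type too. Whether a single fall of the main cell type may account for the higher lists cannot be told apart, as the list medians differed by 0.75 (interval 0.533 to 1.27, permutation p = 0.0408) with the erythroid list, whose globins are near the top of the scale, and by 0.492 (p = 0.221) without it. A less pure column fraction and a change in the placenta itself cannot be told apart, because Cd9 at −1.22 goes with both and no unsorted sample was analysed here.

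The cell cycle list was lower by a median of 0.51, or 0.33 without Met KO replicate 1. Dilution of trophoblast RNA could give this. The median of 5 general trophoblast genes, chosen after their values were seen, lay above it by 0.56 (interval −0.13 to 0.72), which leaves dilution open. Krt8 (+0.068), Krt18 (+0.046), Ets2 (+0.15) and Tfap2c (−0.23) are near the top of the scale. Gata3, away from the top, was at −0.64 (8.45 and 7.40 on the Met KO arrays, limma adjusted p = 0.321), and the low end of the interval rests on it. A lower rate of division in Met KO trophoblast, the biological reading, stays open and untested.

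Genes near Met are a place where DNA of the strain in which an allele was made can remain. Strain DNA linked to the Met allele, acting on genes near it, as the whole cause is argued against by the run of 995 measured genes on either side of Met to the ends of its chromosome, which held 4.83% of the genes past the threshold (45 of 932) and 5.48% of all placed genes. Ptprz1, near Met but at background in both groups, also passed (+1.44) and was not counted. Just short of the threshold (limma adjusted p = 0.0512 to 0.0669) lay rises of Cav1 (+1.89), Cav2 (+1.64), Wnt2 (+0.90) and D830026I12Rik. The last was at background in wild type (3.87, against 6.45 in Met KO), and no bound was computed for it. Falls of Arf5 (−0.95), Lsm8 (−0.69), Zfp800 (−0.68), Ing3 (−0.65) and Ndufa4 (−0.63) were just short of the threshold too. In gene order the rises just short of it lay on either side of Met between Mdfic and Cttnbp2, which passed. Tes (+0.22) and Capza2 (−0.18) also lay in that stretch, and these falls lay outside it. The stretch was picked after its values were seen and was not tested. Among the 40 nearest genes above background in a group 4 rose, namely Cttnbp2 (+3.04), Tfec (+1.73), St7 (+1.48) and Mdfic (+1.27), named after their values were seen. DNA linked to the Met allele, or a local effect of the allele, may account for these 4 rises, but 5.81% of 13965 such windows held as many, against 1.26 expected (one-sided exact hypergeometric p = 0.0361), so this stays open. More RNA from other cell types was not excluded for them, and the strains were not given in the sources used here.

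A hypothesis that neighbouring genes may change together was tested on gene order. There were 38 neighbouring pairs with different symbol stems and both genes past the threshold in one direction, where 10000 shuffles gave a median of 22, with 31 as the upper end of their central 95% and a one-sided permutation p = 0.0010. Without genes at the control level in both groups, a check added after the result was seen, there were 41 pairs against a median of 27 and an upper end of 37 (one-sided permutation p = 0.00580). Pairs, named after their values were seen, include Slc22a18 with Phlda2 (−2.30 and −3.59), which share an imprinted domain, F13a1 with Ly86 (+2.72 and +2.50), and Aif1 with Lst1 (+2.17 and +1.71). F13a1 and Aif1 are on the macrophage list, so a shared cell type of origin may underlie part of the excess. The rule on symbol stems also leaves in some related genes, such as Cd48 with Slamf1 (+1.58 and +1.51), so the count is not free of them.

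Symbol families were searched for shared direction. Of 618 tests 0 passed an adjusted p of 0.05, the lowest being Tlr genes, 4 of 11 higher (adjusted p = 0.0783), and Ifi genes, 4 of 13 higher (adjusted p = 0.0812). For the real split of the 4 arrays 932 genes passed, and the highest of the other splits gave 0; 1 of the 3 splits gave as many as the real one, and 3 splits are too few for a share under 0.05.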
